A study of Homo sapiens with 18 samples.

How the data were processed

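Polyadenylated RNA of LNCaP cells was sequenced in 6 groups of 3 replicates, which the labels call biological. Reads were quality-checked with FastQC, aligned with STAR 2.6.1c to GRCh38.p12, counted with featureCounts and compared with DESeq2, per the submitters' processing notes. The annotation release, strandedness and filters are not given in the sources used here. RNA integrity numbers lay between 9.5 and 10, per the labels.

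The 5 tables used hold the authors' own comparisons, with 27599 rows each and no values per sample. The average normalized count of a gene over all samples is a signal that the authors deposited on a linear scale (baseMean, per the file headers). The fold change and its standard error are log2 values deposited by the authors, the Wald statistic is a score deposited by the authors, and the p-value and adjusted p-value are as deposited. In every row the statistic equalled the log2 fold change over its SE, the p-value was that of a two-sided normal test, and the adjusted p was Benjamini-Hochberg (BH) over the genes left after independent filtering. That filtering left out 6421, 7491 and 12307 rows in the comparisons with DHT and 0 in the 2 without it; a gene without an adjusted p was not called and kept no value. Averages were identical in all tables, as a single normalization of the 18 samples would give.

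In 25 rows a date stood in place of a gene symbol, as spreadsheets convert some names; these were left out, which leaves 27574 genes. Coordinates, transcript length and GC content came from GENCODE release 29 on GRCh38, matched by symbol for 27292 genes (99.0%). That release may not be the one the authors used. Group means and dispersions were recovered from the averages, fold changes and SE. The dispersions from the other tables lay within 5% of those from the DHT table for 94.4% to 100% of genes averaging at least 100. These recovered values are unreliable for genes of low count such as STEAP4.

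Genes were called at an adjusted p under 0.05 from the authors' DESeq2 tables. Further comparisons were made from the log2 values by Wald tests with BH over all genes. The difference between compounds with DHT, and each compound with DHT against vehicle, used the mean of the 2 squared SE. That is the variance when the shared group cancels and all groups involved have equal variance. Interactions with DHT used the sum of the squared SE. Gene lists were tested with camera (cameraPR, limma 3.58.1 in R 4.3.3) on the statistic, with a preset correlation of 0.01 and BH over 23 lists per comparison. Without values per sample no correlation could be estimated, so 0.05 was tried instead. Lists were written from general knowledge, and 15 of their entries were absent from the tables. The median of a list and its test differed in sign in 28 of 230 tests, of which 0 were called. Other steps used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.

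Comparisons, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took up to 10 higher and 10 lower called genes by log2 change that averaged at least 100, up to 5 and 5 without DHT, a panel of 12 genes, and up to 4 members per list. The fixed plan was for counts per sample and, without them, for the authors' statistics, which applied here. The GC correction was added after seeing the data: from each log2 change it subtracts the median of nuclear genes of like GC (20 bins, genes averaging at least 100) and keeps the SE. The difference between the compounds without DHT was also added then.

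The Wald steps were tested on simulated values for 27574 genes, with 50 genes changed at each size. For the difference between compounds with DHT, 22.0% of genes changed by 0.5, 50.0% at 1, 92.0% at 2 and 100% at 3 on the log2 scale were called, and 9 of 141 calls were of unchanged genes. For the enzalutamide interaction the shares were 12.0%, 34.0%, 74.0% and 90.0%. With camera, 5.5% of 200 unchanged lists of 20 genes and 96.0% of 50 lists shifted by 1 had p under 0.05. All simulated values had independent errors, and the Wald steps also had known SE and equal variance in every group. Those are the conditions the tests assume, and no trend with GC content was simulated. The shares therefore need not hold for the deposited values. Depth per library being unknown, precision is given by the SE alone. Antisense and overlapping genes cannot be separated where strand was not used, and the p-values measure the spread between cultures of 1 line.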

Results

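The samples were cultures of LNCaP, a human prostate cancer line that carries a functional androgen receptor and responds to androgen. The cells had spent 48 h in medium with charcoal-stripped serum, which removes most steroid hormones, and were then treated for 6 h. Polyadenylated RNA was sequenced on the BGISEQ-500 platform from 6 groups of 3 biological replicates, 18 samples in all. A pair of groups received the vehicles alone or 10 nM dihydrotestosterone (DHT), the potent natural androgen. The other 4 groups received enzalutamide, a clinical antagonist of the androgen receptor, at 1.5 µM, or VPC-13789, a compound known from the labels by its code, at 3 µM, each with DHT and without it. The doses are stated for the DHT arms and are taken to be the same in the arms without DHT. Per the labels, doses followed published IC90 values, so the 2 compounds were compared at different concentrations. The series title concerns VPC-13822 and binding function-3, a surface of the androgen receptor; how VPC-13789 relates to that compound is not stated.

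The values are the authors' own comparisons, as log2 fold changes with standard errors (SE) and adjusted p-values for 27574 genes. Depth per library is unknown here, because no values per sample were analysed. The average normalized counts summed to 21213074, and 10819 genes averaged at least 100. The SE had a median of 0.27 on the log2 scale among those 10819 genes in each of the 5 comparisons.

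The comparison of DHT with vehicle asks which genes answered androgen within 6 h. DHT changed 395 genes, of which 312 rose and 83 fell, and 178 of the rises and 22 of the falls were at least 2-fold. In the authors' deposited table the protease gene TMPRSS2 rose 9.37-fold (log2 3.23, SE 0.10, adjusted p = 1.72e-212). The authors' deposited table gives KLK3, which encodes prostate-specific antigen, a log2 change of 1.39 (SE 0.28, adjusted p = 0.00011), and its neighbour KLK2 a log2 change of 2.55 (SE 0.30, adjusted p = 1.53e-14).

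Among genes averaging at least 100 normalized counts, those with the highest changes in the authors' deposited table included CHRNA2 (4.13, SE 0.38), SGK1 (4.03, SE 0.24), TMPRSS2, MAF (2.96, SE 0.38), PMEPA1 (2.88, SE 0.13), FKBP5 (2.80, SE 0.22), KLK2, RHOU (2.42, SE 0.45) and SLC45A3 (2.36, SE 0.27). FKBP5 encodes a co-chaperone of steroid receptors, SGK1 a serum- and glucocorticoid-regulated kinase, and PMEPA1 an inhibitor of TGF-β signalling. STEAP4, a metalloreductase gene averaging 11.1 normalized counts, had the panel's highest log2 change in the authors' deposited table, 6.32 (SE 1.03, adjusted p = 1.51e-07), from a vehicle level near 0. Of the genes averaging at least 100, the 10 that fell furthest were OPRK1, the kappa opioid receptor gene, which fell 4.01-fold (adjusted p = 0.00656) in the authors' deposited table, and then MID1, OSR2, SPTLC3, BAMBI, ID3, HOXC13-AS, DEPTOR, SDC4 and GUSBP1, between -1.32 and -0.91. Of these, BAMBI, a decoy receptor of TGF-β family signalling, had the lowest adjusted p in the authors' deposited table (log2 -1.05, SE 0.08, adjusted p = 1.08e-34). With a correction for GC content, added after seeing the data, MID1 was no longer called (adjusted p = 0.0774), at -1.24 against -1.32 before, with the same SE of 0.38.

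On GRCh38, TMPRSS2 lies on chromosome 21 at 41464551 to 41531116, on the minus strand. KLK3 and KLK2 are adjacent paralogs on the plus strand of chromosome 19, at 50854915 to 50860764 and 50861568 to 50880567, so reads of the shared sequence may be split between them. FKBP5 and SGK1 lie on the minus strand of chromosome 6, at 35573585 to 35728583 and 134169246 to 134318112. BAMBI is on the plus strand of chromosome 10 at 28677342 to 28682939. Each span is the whole annotated gene, and the counts are of its exons.

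Of the 20 genes of an androgen receptor activity score, 10 rose, none fell and 10 were not called (camera, adjusted p = 5.14e-153); adjusted over the list alone, 16 rose. The median log2 change of the list was 1.57. Among 99 genes of the hallmark androgen response, 27 rose and 72 were not called, with 34 rising when adjusted over the list alone (adjusted p = 3.82e-97). Of 12 androgen-repressed genes, 3 fell, and 3 fell when adjusted over the list alone (adjusted p = 1.05e-08). They included CAMK2N1, an inhibitor of CaM kinase II, and the chemokine receptor gene ACKR3, at -0.60 (SE 0.07) and -0.67 (SE 0.14) in the authors' deposited table. Among 10 glucocorticoid-regulated genes, 5 rose, and 5 rose and 1 fell when adjusted over the list alone (adjusted p = 4.08e-52). The transcription factor genes ZBTB16 and CEBPD were among the risers, 3.51-fold and 2.07-fold in the authors' deposited table. SGK1 and FKBP5 belong to both the glucocorticoid-regulated and the hallmark list, so the results of these lists are not independent.

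Smaller shifts of lists were called for the unfolded protein response (15 genes, median 0.21, adjusted p = 0.0101), polyamine metabolism (8 genes, median 0.21, adjusted p = 0.0204) and immediate early genes (15 genes, median 0.28, adjusted p = 0.0264). A single member of each rose, namely HERPUD1, SMS and NR4A1, at 0.72 (SE 0.19), 0.37 (SE 0.10) and 1.27 (SE 0.29) in the authors' deposited table. Adjusted over the list alone, 1 gene of the unfolded protein response, 1 of polyamine metabolism and 2 immediate early genes rose. A correction for GC content ended the call of the immediate early genes (adjusted p = 0.148), and a preset correlation of 0.05 ended the calls of all 3 lists, at 0.0502, 0.0502 and 0.0984. Lists of S phase genes (adjusted p = 0.675), mitosis (0.9), heat shock (0.806), interferon response (0.407) and markers of stromal, basal, blood and immune cells (0.734) were not called. The p53 targets were not called either, and their median (-0.13) and their test, which pointed higher (adjusted p = 0.675), differed in sign.

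**Figure D1:**
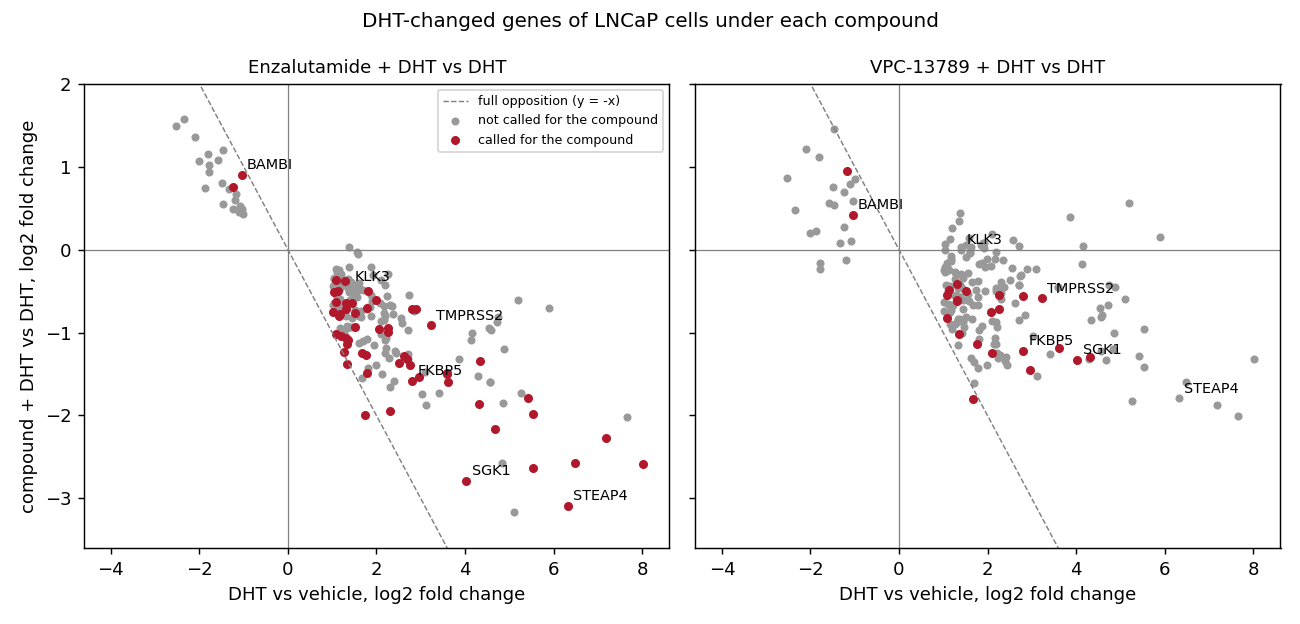
Each point is 1 of the 200 genes called for DHT with at least a 2-fold change, placed by its log2 fold change with DHT (x axis) and by its log2 fold change with a compound added to DHT (y axis), for enzalutamide on the left and VPC-13789 on the right. Red points were called for the compound and the dashed line marks full opposition; of the 178 induced genes, 54 were called lower with enzalutamide and 21 with VPC-13789.

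Enzalutamide added to DHT asks how far a known antagonist reverses the androgen response. Against DHT alone, 86 genes changed, of which 81 fell and 5 rose. In the authors' deposited table SGK1 fell furthest among well-expressed genes (log2 -2.79, SE 0.23, adjusted p = 1.78e-30), and FKBP5 fell with a log2 change of -1.58 (SE 0.22, adjusted p = 2.59e-09). TMPRSS2 and PMEPA1 fell too, at -0.91 (SE 0.10) and -0.72 (SE 0.13) in the authors' deposited table. KLK3 and KLK2 were not called, at -0.44 (SE 0.28, adjusted p = 1) and -0.82 (SE 0.30, adjusted p = 0.684) in the authors' deposited table.

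The other 8 of the 10 furthest falls among genes averaging at least 100 normalized counts were MAF, TIPARP, ERRFI1, NDRG1, CYP2U1, CRISPLD2, PRKCA and NCAPD3, ranging from -1.54 to -1.02 in the authors' deposited table. NDRG1 is a stress- and hypoxia-responsive gene, ERRFI1 encodes a feedback inhibitor of EGF receptor signalling, and NCAPD3 a condensin subunit. The 5 genes that rose were BAMBI (0.90, SE 0.08), OSR2 (0.76, SE 0.20), SDC4 (0.46, SE 0.09), GRB10 (0.41, SE 0.09) and CAMK2N1 (0.31, SE 0.07) in the authors' deposited table, and each of the 5 had fallen with DHT. STEAP4 fell to a log2 change of -3.09 (SE 0.67) in the authors' deposited table, at its low count. ORM1 and ORM2 also fell, at -2.58 (SE 0.53) and -2.63 (SE 0.42) in the authors' deposited table, but they are near-identical copies whose reads may be shared and were picked after their values were seen.

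Of the 20 score genes 5 fell and 15 were not called, with 7 falling when adjusted over the list alone (median -0.63, adjusted p = 2.49e-40). Of the 99 hallmark genes 13 fell and 86 were not called, with 20 falling when adjusted over the list alone (adjusted p = 7.55e-49). Among glucocorticoid-regulated genes 3 fell, and 5 fell and 1 rose when adjusted over the list alone (adjusted p = 6.56e-24). The androgen-repressed list moved up, with 1 of 12 called and 2 when adjusted over the list alone (median 0.28, adjusted p = 2.48e-08). Hypoxia genes moved down (1 of 13 called, 2 adjusted over the list alone, adjusted p = 3.85e-05), as did the unfolded protein response (median -0.18, adjusted p = 0.00355), for which 0 members were called, also when adjusted over the list alone. Immediate early genes were lower (median -0.15, 0 called, 1 adjusted over the list alone, adjusted p = 0.0169), and so were targets of the aryl hydrocarbon receptor (1 of 6 called, 1 adjusted over the list alone, adjusted p = 0.0354). With a preset correlation of 0.05 these last 2 lists were not called (0.0631 for each). The called members of the hypoxia and aryl hydrocarbon receptor lists, NDRG1 and TIPARP, were genes that DHT had raised. Their log2 changes with DHT were 1.67 (SE 0.24) and 1.78 (SE 0.38) in the authors' deposited table. NDRG1 is also a hallmark androgen response gene, so these calls do not show a response apart from androgen. Mitosis (adjusted p = 0.953), S phase genes (0.79) and cholesterol synthesis (0.666) were not called.

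VPC-13789 added to DHT changed 42 genes, of which 38 fell and 4 rose. In the authors' deposited table FKBP5 fell with a log2 change of -1.22 (SE 0.22, adjusted p = 0.000107), SGK1 with -1.33 (SE 0.22, adjusted p = 6.86e-06) and TMPRSS2 with -0.59 (SE 0.10, adjusted p = 1.78e-05). KLK3 stood at -0.00 (SE 0.28, adjusted p = 1) and PMEPA1 at -0.24 (SE 0.13, adjusted p = 0.406) in the authors' deposited table, neither called. With the GC correction PMEPA1 was called (-0.48, adjusted p = 0.0157).

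Among genes averaging at least 100 normalized counts and not known by a clone name alone, the 10 furthest falls were MAF (-1.45, SE 0.38), SGK1, FKBP5, ERRFI1 (-1.14, SE 0.23), INSIG1 (-1.07, SE 0.21), CYP2U1 (-1.02, SE 0.21), NCAPD3 (-0.82, SE 0.13), CENPN (-0.76, SE 0.11), VLDLR (-0.67, SE 0.17) and LRIG1 (-0.62, SE 0.13) in the authors' deposited table. INSIG1 encodes a sterol-responsive regulator of cholesterol synthesis and VLDLR a lipoprotein receptor. IL4R and BAMBI rose, at 0.63 (SE 0.15) and 0.42 (SE 0.09) in the authors' deposited table. The GC correction ended the calls of FKBP5 (-0.70, adjusted p = 0.0648), VLDLR (-0.26, adjusted p = 0.955) and IL4R (0.28, adjusted p = 0.646).

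Log2 changes in this comparison went with GC content across 10753 nuclear genes (Spearman rho = 0.816; genes are not independent replicates). The median was -0.67 in the eighth of genes with the lowest GC and 0.47 in the eighth with the highest. The same rho was 0.498 for DHT, -0.323 for enzalutamide with DHT, and 0.775 and 0.741 for enzalutamide and VPC-13789 without DHT. After centring on GC, 631 genes were called for VPC-13789 with DHT, 379 higher and 252 lower, and 25 of the 42 were among them. Of the 606 genes that this added, 149 had an unadjusted p under 0.05 as deposited.

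Of the 20 score genes 4 fell and 16 were not called, with 9 falling when adjusted over the list alone (median -0.94, and -0.54 after GC centring; adjusted p = 5.54e-14 and 6.95e-10). Of the 99 hallmark genes 11 fell and 88 were not called, with 25 falling when adjusted over the list alone (median -0.55, and -0.25 after GC centring; adjusted p = 6.54e-25 and 1.89e-09). Among 24 cholesterol synthesis genes 1 fell, and 7 fell when adjusted over the list alone; the list was called lower (adjusted p = 0.0154) but not after GC centring (adjusted p = 0.0716). SQLE and MSMO1 were at -0.75 (SE 0.22) and -1.13 (SE 0.35) in the authors' deposited table, neither called. ATF4 targets, a set tied to amino acid stress, and metallothioneins were called higher (adjusted p = 0.0146 and 0.00234) but not after GC centring (0.202 for each), with 1 ATF4 target called lower and 0 metallothioneins called; adjusted over the list alone, 1 ATF4 target and 3 metallothioneins rose and 1 ATF4 target fell. The 13 mitochondrially encoded protein genes had a median of 0.74 (0.94 after GC centring, adjusted p = 5.74e-08), and 20 ribosomal protein genes a median of 0.27 (adjusted p = 0.00234). In either list 0 members were called, also when adjusted over the list alone. The mitochondrially encoded genes lay close together, from 0.56 to 0.81. A preset correlation of 0.01 may be too low for them, and their adjusted p too small. Glucocorticoid-regulated genes were not called as a set (2 fell, 2 adjusted over the list alone, adjusted p = 0.0568, and 0.00101 after GC centring), and their median of 0.03 and their test, which pointed lower, differed in sign.

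**Figure D2:**
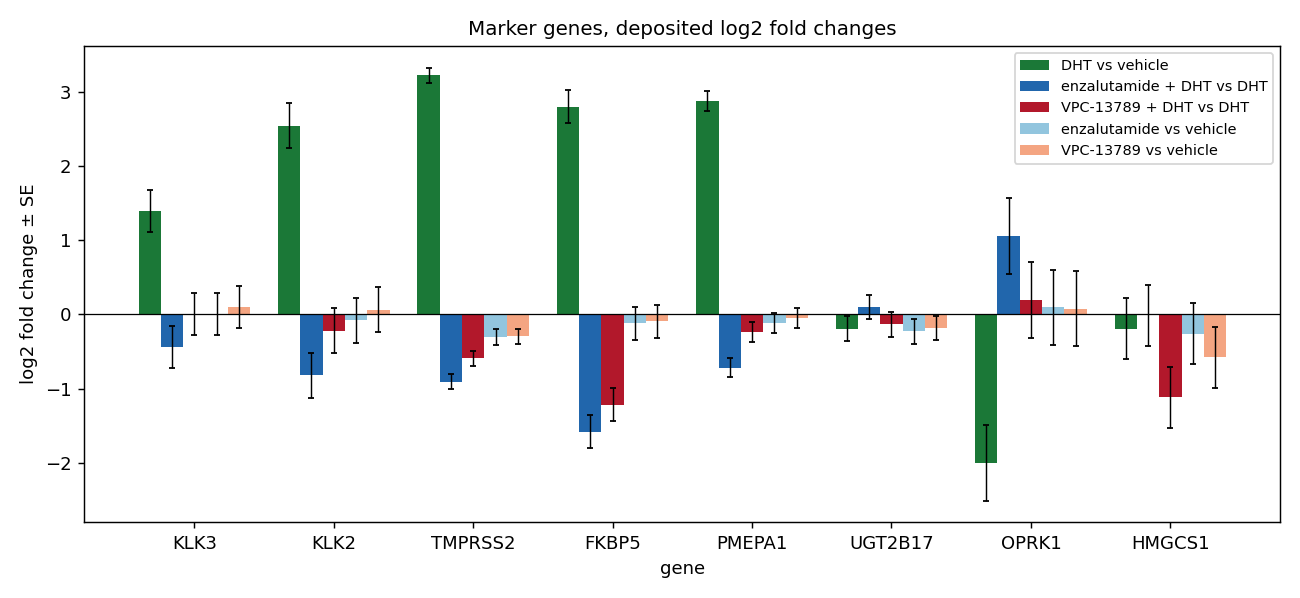
Bars give the log2 fold change of 8 marker genes in the 5 deposited comparisons, and error bars the SE. TMPRSS2 and FKBP5 were higher with DHT and lower when either compound was added, while KLK3 stood at -0.44 with enzalutamide and -0.00 with VPC-13789.

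How far each compound opposed DHT was read from the 178 genes that DHT raised at least 2-fold. Enzalutamide lowered 54 of them and VPC-13789 lowered 21, and neither raised any. With GC centring, which left 176 genes, the counts were 49 and 39, and VPC-13789 raised 1. The sign was opposite to that of DHT for 177 genes with enzalutamide and 158 with VPC-13789. The median opposition, the share of the DHT log2 change that a compound took back, was 41.3% for enzalutamide and 26.0% for VPC-13789. These comparisons share the DHT libraries, and simulated compounds without effect gave medians of 6.18% and 5.98% (highest of 200 draws 9.35% and 9.72%), with at most 1 gene called. The simulated sets of DHT-induced genes were larger than the observed one, with a median of 310 genes (268 to 352). Among 22 genes that DHT lowered at least 2-fold, 2 were called higher with each compound, and the median opposition was 54.7% and 36.2%.

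Of the 81 genes lower with enzalutamide 79 had risen with DHT (1.25 expected of independent lists), and of the 38 lower with VPC-13789 34 had (0.702 expected). The 28 genes lower with both compounds included SGK1, FKBP5, TMPRSS2, ERRFI1, MAF, CYP2U1 and NCAPD3, against 0.192 expected of independent lists. Simulated groups without effect shared at most 1 call. Part of the excess may come from the shared DHT libraries, which cannot be split here.

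The difference between the compounds with DHT was tested directly, and 3 genes passed. SGK1 was higher with VPC-13789 than with enzalutamide by 1.46 (SE 0.22, Wald test, adjusted p = 1.41e-06), CHST2 was higher by 1.50 (SE 0.30, adjusted p = 0.00634) and BAMBI lower by 0.48, a difference of -0.48 (SE 0.08, adjusted p = 0.000122). CHST2, a sulfotransferase gene averaging 27.8 normalized counts, lies below the level set for named genes and is given because only 3 genes passed. Another 1512 genes had an unadjusted p under 0.05 without passing, among 1515 in all. TMPRSS2, FKBP5 and KLK3 did not pass with the values as deposited: the 95% interval of the difference ran from 0.12 to 0.52 for TMPRSS2, from -0.07 to 0.80 for FKBP5 and from -0.11 to 1.00 for KLK3. With GC centring FKBP5 did pass (0.90, adjusted p = 0.00388), and the count rose to 701, with 450 higher and 251 lower. As a set, the 178 DHT-induced genes were higher with VPC-13789 (136 of 178, median difference 0.33, camera p = 1.57e-17, n = 178 genes), though this set was chosen on these samples and genes are not independent replicates. The 20 score genes were not called as a set (adjusted p = 0.463), their median of -0.10 and their test, which pointed higher, differing in sign. The 99 hallmark genes were not called either (adjusted p = 0.757), but were higher with VPC-13789 after GC centring (adjusted p = 0.00775). Glucocorticoid-regulated genes were higher with VPC-13789 (1 called, 4 adjusted over the list alone, adjusted p = 5.23e-05), and androgen-repressed genes were lower (0 called, also adjusted over the list alone, adjusted p = 0.000345, and 0.198 after GC centring). Mitochondrially encoded (adjusted p = 1.55e-06), ribosomal protein (0.000905), metallothionein (0.0114) and immediate early genes (0.0304) were higher with VPC-13789. For the mitochondrially encoded genes, which lay close together with VPC-13789 and DHT, the adjusted p may be too small. The calls of metallothioneins (0.465) and immediate early genes (0.632, now lower) ended with GC centring.

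Each compound with DHT was also set against vehicle. With enzalutamide 109 genes differed, 101 higher and 8 lower, of which 100 and 8 were called in the same direction for DHT. With VPC-13789 300 differed, 202 higher and 98 lower, of which 168 and 38 were, and 94 were not called for DHT. TMPRSS2 remained above vehicle by 2.32 (SE 0.10) under enzalutamide and 2.64 (SE 0.10) under VPC-13789. KLK3 was 0.95 above vehicle under enzalutamide (SE 0.28, adjusted p = 0.157), not called, and 1.39 under VPC-13789 (SE 0.28, adjusted p = 0.000212). Of the 20 score genes 7 stayed higher under enzalutamide and 8 under VPC-13789, and 11 and 10 when adjusted over the list alone. With GC centring the VPC-13789 count became 1473, with 939 higher and 534 lower, and 1192 of these genes were not called for DHT with the same centring.

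Without DHT the compounds show what they do to cells with little androgen. Enzalutamide changed 1 gene: ZBTB16, a zinc finger transcription factor gene, fell with a log2 change of -0.59 (SE 0.12, adjusted p = 0.0139) in the authors' deposited table. VPC-13789 changed 0 genes at that threshold in the authors' DESeq2 analysis, with 212 at an unadjusted p under 0.05 against 186 for enzalutamide, and the lowest adjusted p, 0.372, belonged to SYTL4. TMPRSS2 was at -0.30 (SE 0.10) with enzalutamide and -0.30 (SE 0.10) with VPC-13789 in the authors' deposited table, not called in either. With GC centring enzalutamide gave 3 calls, 2 of them higher, and VPC-13789 gave 1.

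The 20 score genes were lower as a set with enzalutamide (median -0.17, adjusted p = 8.8e-05) and with VPC-13789 (median -0.15, adjusted p = 0.00174). In each case 0 members were called and 2 fell when adjusted over the list alone. The hallmark genes were lower with enzalutamide (adjusted p = 0.00133, and 0.293 after GC centring; 0 called, 1 adjusted over the list alone) and with VPC-13789 (adjusted p = 0.000296, and 0.035 after GC centring; 0 called, 2 adjusted over the list alone). VPC-13789 without DHT also moved cholesterol synthesis genes down (19 of 24 below 0, median -0.19, adjusted p = 3.1e-07; 0 called and 1 when adjusted over the list alone). Fatty acid synthesis genes were lower (median -0.12, adjusted p = 0.000891; 0 called, 1 adjusted over the list alone) and ATF4 targets higher (median 0.14, adjusted p = 0.000458; 0 called, also adjusted over the list alone). INSIG1 was at -0.85 (SE 0.21) in the authors' deposited table, not called. Mitochondrially encoded genes were higher with enzalutamide (median 0.32, adjusted p = 8.8e-05) and VPC-13789 (median 0.30, adjusted p = 0.000432), with 0 of 13 called in each, also when adjusted over the list alone. With DHT alone their median was 0.27 (adjusted p = 0.0803, and 0.0332 after GC centring), and these 3 comparisons share the vehicle libraries.

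Whether a compound acted differently with and without DHT was tested as an interaction. For enzalutamide 21 genes passed, 19 with a lower log2 change with DHT than without it and 2, BAMBI and LINC01128, with a higher one. SGK1 led, with a difference of -2.95 (SE 0.35, Wald test, adjusted p = 6.55e-13), followed in adjusted p by FOSL2, an AP-1 subunit gene, at -0.92 (SE 0.13, adjusted p = 7.99e-08). For VPC-13789 0 genes passed the same Wald test, with 394 at an unadjusted p under 0.05, and CENPN (difference -0.70, SE 0.16) and F5 (-1.84, SE 0.42) shared the lowest adjusted p, 0.345. With GC centring 15 of the 21 passed for enzalutamide, of 24 in all, and 35 genes passed for VPC-13789, 24 higher and 11 lower. The score genes as a set were lowered more with DHT than without it by enzalutamide (2 called, 4 adjusted over the list alone, adjusted p = 1.55e-12) and by VPC-13789 (0 called, 1 adjusted over the list alone, adjusted p = 6.82e-08). Both list results are from the values as deposited. For VPC-13789 the medians by GC eighth spanned 1.14 with DHT and 0.32 without it, so part of its list result may reflect that GC-linked shift.

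**Figure D3:**
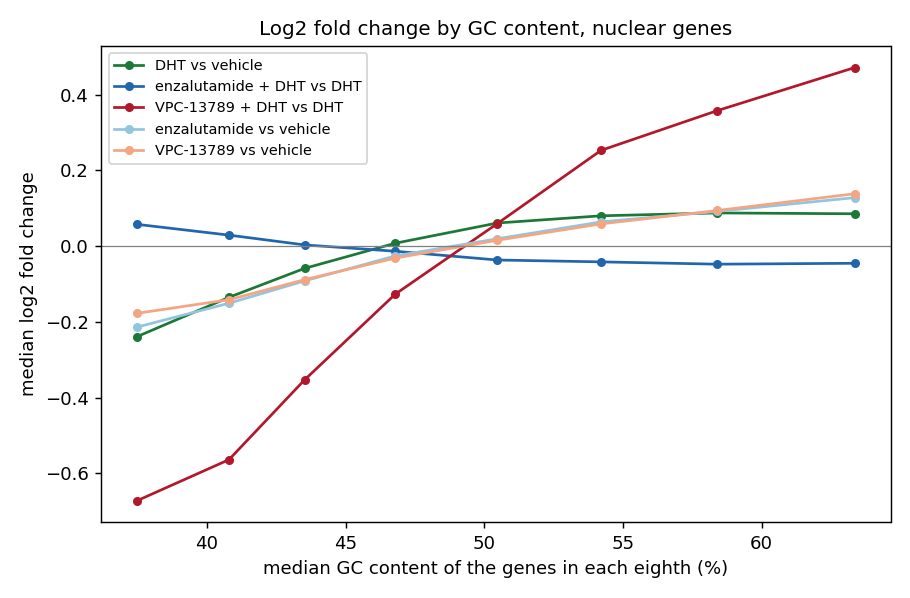
Points give the median log2 fold change (y axis) of 10753 nuclear genes in 8 equal groups by GC content (x axis, median GC of the group in percent), with 1 line per deposited comparison. VPC-13789 with DHT runs from -0.67 at the lowest GC to 0.47 at the highest, and enzalutamide with DHT from 0.06 to -0.05.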

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

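In this part the tests chosen only after the result was seen are those of the GC trend in nuclear and mitochondrial genes, of its correlation with enzalutamide, of its size against SE, of the ratio of SE between compounds and of the set difference between compounds.

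For 21 genes the effect of enzalutamide differed with and without DHT by the interaction test. Those with a lower change with DHT than without it were SGK1 (-2.95), CASC10 (-2.21), CHST2 (-2.03), F5 (-1.81), FKBP5 (-1.46), GADD45G (-1.12), SLC41A1 (-0.96), IGF1R (-0.94), FOSL2 (-0.92), NCAPD3 (-0.91), CENPN (-0.90), HS3ST1 (-0.77), TMPRSS2 (-0.61), ANKH (-0.59), EFNA5 (-0.54), TNFRSF10B (-0.53), TBC1D1 (-0.52), SHROOM3 (-0.50) and CHKA (-0.47), each a difference of log2 changes. LINC01128 (0.60) and BAMBI (0.62) went the other way. With GC centring 6 of the 21 lost their call, namely CASC10 (-2.11, adjusted p = 0.0762), CHST2 (-1.89, 0.0627), GADD45G (-0.94, 0.135), TMPRSS2 (-0.53, 0.207), TNFRSF10B (-0.48, 0.0775) and CHKA (-0.40, 0.163). Their SE of 0.53, 0.47, 0.25, 0.15, 0.12 and 0.11 were kept, and each difference moved by less than its SE, so the lost calls do not show that GC accounts for them.

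The first pattern is the GC-linked shift with VPC-13789 and DHT, where medians by GC bin accounted for 66.1% of the variance of log2 changes over nuclear genes. The tables argue against none of the explanations tested. Mitochondrially encoded genes stood 0.94 above nuclear genes of the same GC, but 0 of 13 were called and they are not part of the nuclear trend, so they do not decide on GC. A response to VPC-13789 stays open. Enzalutamide without DHT, which shares no library with it, correlated at 0.834 across genes, and at 0.586 after GC centring. Its medians by GC eighth, however, ran only from -0.21 to 0.13, against -0.67 to 0.47 with VPC-13789 and DHT. Those of VPC-13789 without DHT ran from -0.18 to 0.14, so without DHT it gave no larger trend than enzalutamide. That does not test a response that needs DHT. The tests on mitochondrial genes and on this correlation had first counted against GC as the whole cause and against a response to VPC-13789. Each was given a further condition after its value was seen, called members for the first and a GC trend of like size for the second, and neither value meets it. Length stays open, with a rho of -0.328 after GC centring. Libraries of the same group may differ along GC content, because the median dispersion of both outer GC eighths pooled was at least 4.62 times that at mid GC in each of 4 classes of expression. Taken apart, the ratio of an outer eighth was as low as 2.69. Whether such libraries fell unevenly on the groups by chance was not decided. The shift reached a median of 1.44 SE in the outer GC eighths, but the SE of single genes is not the spread of a median over many, and no values per sample were analysed. That test replaced an earlier one after its value was known: the spread of the statistic about the median of each outer eighth, at most 0.340, leaves out any shift common to the eighth and could not decide either.

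The second pattern is that 42 genes were called for VPC-13789 against 86 for enzalutamide. SE were alike (median ratio 1.00), so larger SE do not account for the fewer calls. Alike SE follow where all groups share a dispersion per gene, and cannot show whether the VPC-13789 libraries were noisier. The ratio of calls stayed at 0.405 with BH over every gene, which argues against independent filtering. With GC centring the ratio was 8.30, which met the bound set beforehand for calls hidden by the GC-linked shift. That reading was withdrawn by a rule added after the value was seen, because only 24.6% of the 606 added genes had an unadjusted p under 0.05 as deposited, so hidden calls cannot be told apart from calls made by the centring itself. A smaller effect at the doses used may account for the difference among DHT-induced genes, which were higher with VPC-13789 than with enzalutamide also after GC centring (camera p = 2.68e-12, n = 176 genes).

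The third pattern is the opposition of DHT-induced genes, 41.3% and 26.0% at the median. Chance values of the shared DHT libraries gave at most 9.72% in 200 simulated draws, below both, though the simulated sets held 268 to 352 genes and not the 178 observed. The observed covariance of log2 changes between DHT and enzalutamide, -0.0351, was smaller in size than the simulated -0.0557, and that between the compounds was -0.00514 against a simulated 0.0561. The correlation between DHT and enzalutamide went the other way, at -0.833 observed and -0.380 simulated, so the part due to shared libraries was not estimated. Whether other splits of the samples give as many calls was not counted, as no values per sample were analysed.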

How the results depend on the processing

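The tests chosen only after the result was seen are the GC centring, SE from recovered group variances and the difference between compounds without DHT; the other alternatives were fixed before the data were examined. Of 168 counts recomputed under alternatives, 115 stayed within 1.5 times the reported value and 53 did not. Of the results for single genes and lists, 993 kept their direction and their side of the threshold, 113 lost a call and 9 changed sign. Another 2, both single genes (PMEPA1 and FKBP5, with GC centring), gained a call. Lists that gained a call are not among these counts. With GC centring these included glucocorticoid-regulated genes with VPC-13789 and DHT, hallmark genes between compounds, and mitochondrially encoded genes with DHT alone.

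With a fold change of at least 2 required, calls were 200 for DHT, 33 for enzalutamide with DHT, 10 for VPC-13789 with DHT, 0 for enzalutamide without DHT, 6 for the enzalutamide interaction, and 58 and 138 for enzalutamide and VPC-13789 with DHT against vehicle. Tested against an absolute log2 change of 0.5, the same calls were 108, 6, 0, 0, 1, 30 and 60, and the difference between compounds had 0. Both settings ask for larger changes by construction. At an adjusted p under 0.01, calls were 22 for VPC-13789 with DHT, 0 for enzalutamide without DHT, 9 for the enzalutamide interaction and 190 for VPC-13789 with DHT against vehicle. At 0.1 the difference between compounds had 7 calls, and 5 with BH over genes averaging at least 100, which tests fewer genes. With the squared SE summed, which is larger by construction, it had 0, and the compounds with DHT against vehicle had 37 and 92. With SE from recovered group variances, the difference between compounds had 2 higher and 1 lower. Against vehicle, enzalutamide with DHT then had 83 higher and 9 lower, and VPC-13789 with DHT 179 higher and 97 lower.

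GC centring gave 631 calls for VPC-13789 with DHT, 3 and 1 for enzalutamide and VPC-13789 without DHT, 701 for the difference between compounds, 35 for the VPC-13789 interaction and 1473 for VPC-13789 with DHT against vehicle, of which 1192 were not called for DHT with the same centring; the cause was not tested for each count. Single genes changed sign with it, none of them called: UGT2B17 with DHT (0.0175), with VPC-13789 and DHT (0.53) and between compounds (0.49), KLK3 with enzalutamide without DHT (-0.0605), and FKBP5 without DHT with enzalutamide (0.0207) and VPC-13789 (0.042). Recentring on the median turned HMGCS1 with enzalutamide and DHT (0.00418) and KLK3 with VPC-13789 and DHT (0.0181), both near 0 before. The cause of these reversals was not tested.

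Of the opposition counts, induced genes called lower with enzalutamide were 27 at an absolute log2 change of at least 2 and 31 with an average of at least 100. For VPC-13789 they were 34 with no fold threshold, 11 at 2 or more, and 39 with GC centring. Repressed genes called higher with enzalutamide were 5 with no fold threshold and 0 at 2 or more. For VPC-13789 they were 0 at 2 or more and 1 with an average of at least 100, and median opposition with no fold threshold was 22.1%. Fold and count limits change which genes enter; for GC centring the cause was not tested.

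Lists called with log2 change in place of the statistic, which gives noisy genes of low count more weight, were 3 for DHT, 2 for enzalutamide with DHT, 3 for VPC-13789 with DHT, 0 and 0 without DHT, 1 between compounds, 0 and 0 for the VPC-13789 and enzalutamide interactions, and 2 and 3 for the compounds with DHT against vehicle. A preset correlation of 0.05 left 4 for DHT and 4 for the enzalutamide interaction. Over all comparisons it left 29 list results the same and ended the calls of 9, not all of which are named here. GC centring gave 5 for the VPC-13789 interaction and turned the immediate early genes between compounds lower (adjusted p = 0.632); the cause was not tested.

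No paired analysis was possible because the files hold no values per sample. For the same reason leaving out each replicate, TMM against DESeq2 size factors, the replicate block and other splits of the samples were not run. Depth per library, which limits how small a change can be called, is unknown here.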

Other observations

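The lipid genes were compared between the compounds without DHT after their values were seen. With VPC-13789 less enzalutamide, cholesterol synthesis genes were lower as a set (camera, adjusted p = 1.86e-08, and 1.51e-08 after GC centring), fatty acid synthesis genes were lower (adjusted p = 0.00236) and ATF4 targets higher (adjusted p = 0.00471). No single gene passed this comparison by the Wald test, with 252 at an unadjusted p under 0.05. The preset correlation of 0.01 could not be checked without values per sample. The adjusted p of these lists, here and against vehicle, may therefore be too small. INSIG1, a sterol-responsive regulator gene, and FADS1, a fatty acid desaturase gene, were called for VPC-13789 with DHT and not for DHT or enzalutamide. In the authors' deposited table INSIG1 was at -1.07 (SE 0.21) with VPC-13789 and DHT and -0.85 (SE 0.21) without DHT, and FADS1 at -0.29 (SE 0.06) and -0.26 (SE 0.06). The corresponding values for enzalutamide with DHT in the authors' deposited table were -0.13 (SE 0.21) and -0.05 (SE 0.06). For INSIG1 the difference between compounds with DHT was -0.93 (SE 0.21, Wald test, adjusted p = 0.0793), which did not pass.

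The other 3 genes called for VPC-13789 and not for DHT were MRPL44, TRIT1 and U73166.1, picked after their values were seen. They had log2 changes of -0.32 (SE 0.07), -0.43 (SE 0.11) and 0.67 (SE 0.17) in the authors' deposited table, and -0.06, 0.00 and 0.31 after GC centring.

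Statistics were narrower than a normal spread in 4 of the 5 deposited comparisons and wider for VPC-13789 with DHT. Among 10753 nuclear genes averaging at least 100, the robust SD of the statistic was 0.363 for enzalutamide with DHT, 0.560 and 0.554 for the compounds without DHT, 0.684 for DHT and 1.98 for VPC-13789 with DHT. The median p was 0.806, 0.708, 0.710, 0.647 and 0.176 in the same order.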
